A study of Mus musculus with 4 samples.

How the data were processed

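The series measured gene expression on 4 Affymetrix arrays, 1 per sample. Total RNA came from LSK cells, the lineage-negative, Sca1-positive, c-Kit-positive bone marrow fraction that holds hematopoietic stem cells and multipotent progenitors. The cells were sorted by flow cytometry from male mice aged 8 weeks, and 2 samples came from wild-type (WT) mice and 2 from mice lacking SRC-3 (KO). The labels call the samples of a group biological replicates but do not say how many mice each sample pooled, and the design text says that arrays were run in duplicate. If the samples of a group did not come from separate mice, the p-values measure only the spread between these samples, which may be technical.

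The authors deposited 1 table of log2 expression values, with 41345 probe sets and 4 array columns. Per the submitters' processing notes, RMA (a method that corrects background, normalizes across arrays and summarises probes on the log2 scale) and Affymetrix Expression Console 1.2.1 were named, without their settings or order. The scale was taken from the values, which ran from 0.375 to 12.8 with medians of 3.84 to 4.05 per array. Filters and the genome build are not given in the sources used here. RMA summaries of dim probe sets are compressed, so a fold of a gene near the low end of the array understates its change. No scanner files, detection calls, scan dates or RNA quality values were used here, so no probe set could be called absent and no array batch could be tested. A sequencing depth does not apply to arrays, and the precision is limited by the 2 arrays per group.

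Probe sets were named from the platform annotation given with the series. It listed 25335 of the 41345 probe sets, of which 23521 had 1 gene symbol and 1814 had several. The other 16010 were not listed. Of the probe sets with 1 gene, 23477 matched a gene identifier in the RefSeq table of assembly GRCm38.p6, and no symbol had to be updated. Probe sets with several genes or none were left out of the main tests. Each gene was represented by its probe set with the highest mean over all 4 arrays, which gave 22180 genes. No filter on dim genes was applied. Values were equal on all 4 arrays for 10 genes.

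KO was compared with WT in limma 3.58.1 (R 4.3.3), with a linear model on the log2 values of all 4 arrays and empirical Bayes moderation with an intensity trend. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Errors of a log2 difference are moderated standard errors (SE), and errors of a group mean are SDs over 2 arrays. A looser count took genes changed at least 1.5-fold at an unadjusted p under 0.01. Gene lists were tested against all other genes with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. The lists were fixed before the data were examined: 22 of pathways and cell states, 1 of immediate early and dissociation stress genes, 8 of markers of other cells, and 1 of Y-linked genes and Xist. Beside each list past the camera threshold stands its adjusted p with the correlation estimated from the data. With 4 arrays that setting leaves few residual degrees of freedom, so its adjusted p can be high whatever the correlation. At the preset correlation camera takes its degrees of freedom from the number of genes, so its small p-values do not reflect how few samples there were. The preset lay far below some estimates, such as 0.19 for mitochondrial ribosome and 0.35 for oxidative phosphorylation genes. For such lists its p-values can be far too small. For others, such as interferon genes at -0.019, it lay above the estimate. The number of members past the threshold adjusted over the list alone is also given, and for some lists the number over all genes.

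The choice of Cdkn1b, Cdkn1c, Rb1, Klf4, Klf6, Mki67, the Mcm genes and some genes of the closing sections was not fixed beforehand. Most other genes named in the text followed a rule that was. It took Ncoa3, then per direction the 15 genes of largest change among those past the threshold with the higher group's mean at or above the median gene (4.32), skipping unnamed gene models. Of these genes 1 kappa V segment is given without its name, and 1 other is not reported in the text. From each list the rule allowed up to 4 members of smallest p and up to 6 members past the threshold, and the text gives not all of the former. The models were tested on simulated data for this comparison, with 200 of 22180 genes changed in each of 20 runs. The test recovered 14.0% of genes changed by 1 on the log2 scale, 91.7% of those changed by 2 and 98.6% of those changed by 3, with 4.59% false calls. In runs with no change, camera called 0 of 640 lists. Genes were simulated independently, so these runs do not test camera on lists whose members vary together.

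Alternatives fixed beforehand were the replicate number as a block, the mean of a gene's probe sets, single probe sets, a filter at the median level, quantile normalization and median centring of the deposited values, no intensity trend, robust moderation, array weights, leaving out each array, and camera with estimated correlation, with ranks, or replaced by fry. Leaving out probe sets with _x_at or _s_at names could not be run because the array has no such names. Restriction to protein-coding genes, removal of a trend with genomic span, and the quiescence list without the immediate early genes were added after the data were seen. The replicate numbers of WT and KO arrays are only numbers in the labels, so the main model had no block. Figures were drawn with matplotlib 3.10.9.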

Results

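Expression was measured in sorted LSK cells of 2 WT and 2 SRC-3 knockout samples, to find the genes whose levels differ in these cells when SRC-3 is missing. SRC-3, encoded by Ncoa3, is a coactivator of nuclear receptors and other transcription factors. LSK cells are the bone marrow fraction enriched for hematopoietic stem cells (HSCs) and multipotent progenitors. Across 22180 genes the 2 KO arrays correlated at r = 0.992 and the 2 WT arrays at r = 0.986, while WT and KO arrays correlated at 0.977 to 0.982. These correlations are across genes, which are not independent replicates. The SD of the log2 differences was 0.279 between the KO arrays and 0.382 between the WT arrays. It was 0.418 to 0.482 between arrays of different genotype. Group means of the Y-linked transcripts were near equal, with Eif2s3y at 7.46 ± 0.51 in WT and 7.48 ± 0.12 in KO (log2, SD, n = 2), and Xist was at 2.29 and 2.35. The list of Y-linked genes and Xist did not pass the test, with a median of -0.03 over 4 members (camera adjusted p = 0.86).

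Ncoa3 (gene identifier 17979, probe set 17379719) fell 4.55-fold in KO. Its mean level was 7.41 ± 0.50 in WT and 5.22 ± 0.18 in KO (log2, SD, n = 2), a difference of -2.19 ± 0.27 (SE, limma adjusted p = 0.038). Both KO arrays, at 5.35 and 5.09, lay below both WT arrays, at 7.76 and 7.05. The KO level remained above that of the median gene on the array, which was 4.32. The gene had 1 probe set, and which part of the gene the knockout removes is not given in the sources used here. Without KO replicate 1 the difference was -2.32 with an adjusted p of 0.716, and without KO replicate 2 it was -2.06 with an adjusted p of 0.551.

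LSK cells of KO mice had 88 genes at higher and 25 at lower levels than WT at an adjusted p under 0.05. All 113 of these genes differed at least 2-fold. Transcripts of the red cell lineage and interferon-inducible transcripts stood among the largest increases, and immunoglobulin V segments among the largest decreases. The median change was 3.33-fold for the higher genes and 2.90-fold for the lower ones. At an unadjusted p under 0.05, 3860 genes differed, against 1109 that chance alone would give. In the looser count, 904 genes were higher and 496 lower by at least 1.5-fold at an unadjusted p under 0.01. After quantile normalization 93 genes were higher and 61 lower, so the share of higher genes was 60.4% instead of 77.9%. In the looser count that share fell from 64.6% to 49.6%. The adjusted count depended on single arrays. Without WT replicate 1 it was 1442 higher and 312 lower, and without WT replicate 2 it was 1730 and 1272. Without KO replicate 1 or KO replicate 2 limma called 0 genes, with 1471 and 1910 genes at an unadjusted p under 0.05. The looser count was 1417 higher and 1098 lower without WT replicate 2, 173 and 103 without KO replicate 1, and 258 and 137 without KO replicate 2.

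Red cell genes were among the largest increases in KO. Ermap, an erythroid membrane protein gene, rose 15.6-fold, from 3.60 ± 0.59 to 7.57 ± 0.02 (log2, SD, n = 2, limma adjusted p = 0.0090). Rhag, which encodes the Rh-associated glycoprotein, rose 12.7-fold. Car1, the carbonic anhydrase of erythroid progenitors, rose 10.8-fold to 11.6, near the top of the array's range. Klf1, a transcription factor of red cell development, rose 5.46-fold. The erythroid genes Add2, for the membrane skeleton protein beta-adducin, and Tspo2 rose 5.69-fold and 5.22-fold.

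Among 21 measured genes of megakaryocyte and erythroid priming, 8 rose and 0 fell past the threshold over all genes, and 12 rose adjusted over the list alone. Aqp1, a water channel, rose 4.86-fold, and Blvrb, a biliverdin reductase, 4.74-fold. Cpox, an enzyme of heme synthesis, rose 2.79-fold, and the transcription factor Gfi1b 2.70-fold. The median of the list was 0.82 higher on the log2 scale (camera adjusted p = 1.9e-13, and adjusted p = 0.22 with an estimated correlation). Markers of erythroblasts, cells that the sort should exclude, moved with it, with a median of 0.74 over 9 members (camera adjusted p = 1.8e-06, and adjusted p = 0.22 with an estimated correlation). Of these 9 markers, Rhag, Ermap and Tspan33 rose past the threshold over all genes, and adjusted over the list alone 7 rose and 1 fell. Ermap belongs to both lists. Markers of platelets and megakaryocytes did not pass the test, with a median of 0.03 over 12 members (camera adjusted p = 0.86), of which 2 were higher and 1 lower adjusted over the list alone, and with each array left out in turn the median ran from -0.054 to 0.038. Within that list Pf4 was 1.27 ± 0.26 higher (adjusted p = 0.099) and Nrgn was at -0.72 ± 0.19 (SE, adjusted p = 0.14).

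**Figure D1:**
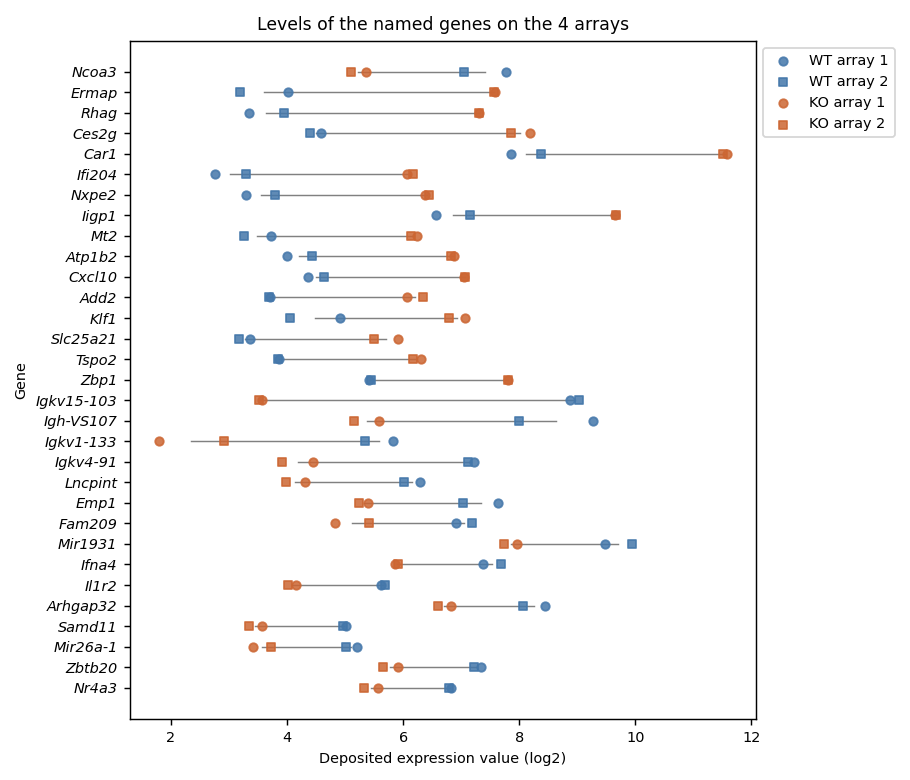
Deposited log2 expression values of Ncoa3, the 15 genes that rose most and the 15 that fell most in KO among those the naming rule allowed, one row per gene, with a point for each of the 2 WT and 2 KO arrays and a grey line joining the group means. Both KO arrays lie beyond both WT arrays for each gene shown, and Ermap spans the widest gap among the genes that rose (3.60 to 7.57).

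Interferon-inducible genes were also among the large increases. Iigp1, an interferon-induced GTPase gene, rose 7.02-fold, from 6.85 ± 0.41 to 9.67 ± 0.01 (log2, SD, n = 2, limma adjusted p = 0.0094). The chemokine gene Cxcl10 rose 5.87-fold, Zbp1, a nucleic acid sensor, 5.20-fold, and Ifi204 8.52-fold. Of 27 measured interferon response genes, 8 rose and 0 fell past the threshold over all genes, and 20 rose adjusted over the list alone. They included Isg15 at 3.49-fold, Usp18 at 3.03-fold, Igtp at 4.58-fold and Bst2 at 2.06-fold. The list's median was 0.78 higher (camera adjusted p = 8.9e-14, and adjusted p = 0.22 with an estimated correlation). Markers of macrophages and dendritic cells moved with it, by a median of 0.13 over 19 members (camera adjusted p = 0.015, and adjusted p = 0.31 with an estimated correlation). In that list the MHC class II genes H2-Aa and H2-Eb1 rose 3.32-fold and 2.78-fold, and Slc40a1, an iron exporter, rose 3.04-fold. Adjusted over the list alone 4 members rose. Without WT replicate 1 the macrophage list had an adjusted p of 0.27 and a median of 0.074, and its adjusted p was 0.13 among genes at or above the median level and 0.068 with camera on ranks. Iigp1 and Ifi204 have close paralogs, so their probe sets may share signal with those copies.

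Genes of the NF-kB and inflammatory list were lower in KO, with a median of -0.27 over 25 members (camera adjusted p = 0.029, and adjusted p = 0.31 with an estimated correlation). Rel, an NF-kB subunit, fell 2.47-fold from 9.97 ± 0.05 to 8.67 ± 0.04 (log2, SD, n = 2, adjusted p = 0.027) and was the member past the threshold. At an unadjusted p under 0.05, 4 members were lower and 3 higher, and adjusted over the list alone 3 fell. Ptgs2, encoding a prostaglandin synthase, was at -0.94 ± 0.18 (SE), Nfkbiz at -0.90 ± 0.20 and Tnfaip2 at 1.01 ± 0.31. Without WT replicate 1 the list's adjusted p was 0.14 and its median -0.15. Without KO replicate 2 the adjusted p was 0.25.

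Genes of mitochondrial translation and respiration were higher in KO as groups, although few passed the threshold one by one. All 57 measured mitochondrial ribosome genes had a higher mean in KO, by a median of 0.72 on the log2 scale, or 1.65-fold (camera adjusted p = 9.1e-26, and adjusted p = 0.31 with an estimated correlation). Over all genes 2 members rose, Mrpl16 by 2.58-fold and Mrpl17 by 2.18-fold, and adjusted over the list alone 48 rose and 0 fell. Mrpl19 was 1.06 ± 0.16 (SE) and Mrps11 0.91 ± 0.15 higher. Of 70 oxidative phosphorylation genes, 67 had a higher mean in KO, with a median of 0.45 (camera adjusted p = 1.7e-16, and adjusted p = 0.31 with an estimated correlation). None passed over all genes in limma, 37 were higher at an unadjusted p under 0.05, and 17 rose adjusted over the list alone. Cyc1, the cytochrome c1 gene of complex III, was 0.91 ± 0.14 (SE) higher, Ndufs8 of complex I 0.94 ± 0.19 higher and Sdhd of complex II 0.84 ± 0.16 higher.

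Genes of 3 other metabolic lists were higher in KO as groups than all other genes, which include dim ones. Genes at or above the median level had a median of 0.045. Grouped by genomic span, such genes had medians from 0.18 down to -0.18 for the longest. The fatty acid oxidation median of 0.17 lay within that range. None of the 3 lists was set against random genes of similar level and span. Whether they rose more than such genes was therefore not tested. Genes of the tricarboxylic acid cycle had a median of 0.43 over 21 members (camera adjusted p = 5.2e-06, and adjusted p = 0.31 with an estimated correlation), with 0 past the threshold over all genes in limma, 11 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone. Idh3a was at 0.84 ± 0.22 and Mdh2 at 0.48 ± 0.13 (SE). Of these members 4 are also in the oxidative phosphorylation list. Antioxidant genes had a median of 0.49 over 24 members (camera adjusted p = 2.7e-06, and adjusted p = 0.22 with an estimated correlation), 13 were higher at an unadjusted p under 0.05 and 8 rose adjusted over the list alone. They included the mitochondrial peroxiredoxin Prdx3 at 1.21 ± 0.19, Txnrd2 at 0.78 ± 0.18 and Gsr at 0.67 ± 0.17 (SE). Fatty acid oxidation genes had a median of 0.17 over 21 members (camera adjusted p = 0.0058, and adjusted p = 0.31 with an estimated correlation). Of these, 5 were higher at an unadjusted p under 0.05, and 3 rose adjusted over the list alone. Acaa2 was at 0.85 ± 0.15 and Eci1 at 0.83 ± 0.17 (SE). Without WT replicate 2 that list's median was 0.071 and its adjusted p 0.094, and among genes at or above the median level the adjusted p was 0.080.

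Regulators of mitochondrial biogenesis and dynamics had a median of 0.25 over 33 members (camera adjusted p = 0.012, and adjusted p = 0.31 with an estimated correlation), and 0 passed over all genes in limma, with 9 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. The mitochondrial transcription factors Tfb1m and Tfb2m were at 0.73 ± 0.19 and 0.83 ± 0.24 (SE), Vdac1 at 0.68 ± 0.16 and Timm23 at 0.48 ± 0.13. Without WT replicate 2 this list's adjusted p was 0.21 and its median 0.13, and without KO replicate 1 the adjusted p was 0.088. It was 0.060 among genes at or above the median level and 0.082 after quantile normalization. Glycolysis genes did not pass the test (camera adjusted p = 0.74), with a median of 0.01, a mean of -0.02 and 23 measured members. At an unadjusted p under 0.05, 1 was higher and 2 were lower, and adjusted over the list alone limma called 0. The glycolysis median was 0.11 without WT replicate 1, -0.13 without WT replicate 2 (adjusted p = 0.051) and -0.041 without KO replicate 2. Slc2a1, the glucose transporter gene, was at -0.56 ± 0.17 and Pgk1 at 0.42 ± 0.17 (SE).

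**Figure D2:**
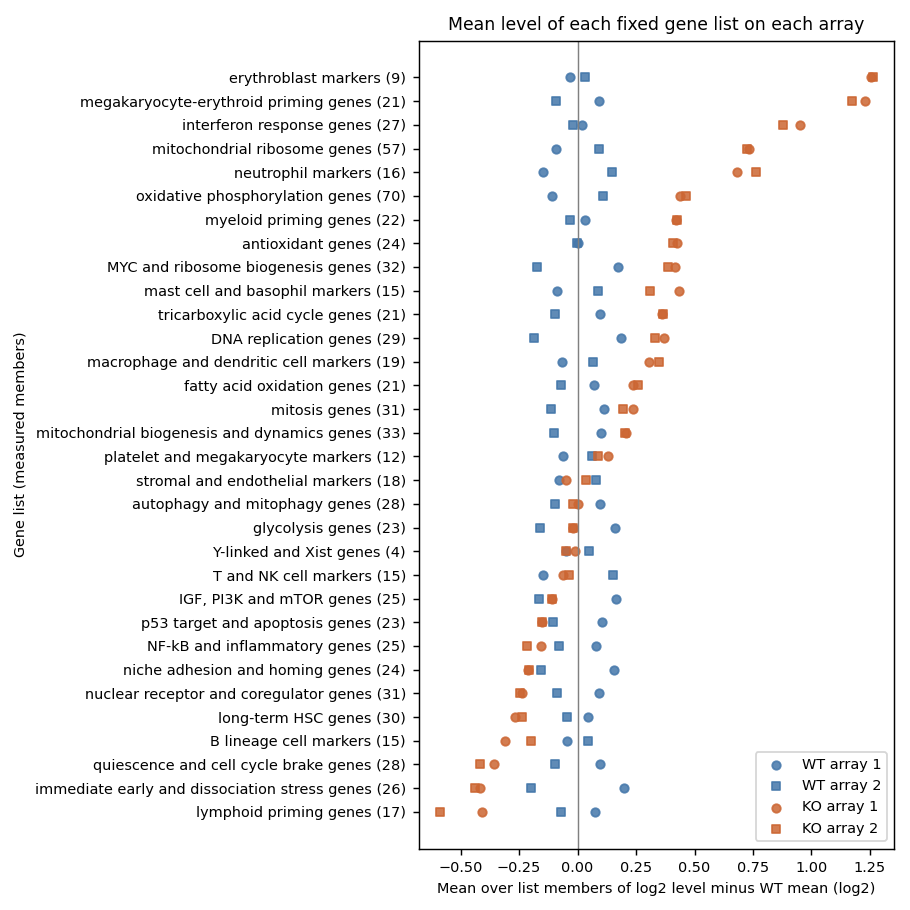
Mean level of the 32 fixed gene lists on each array, as the mean over members of the log2 value minus the WT mean of the gene (x axis, log2), with 1 point per array and the number of measured members in parentheses. Both KO arrays lie beyond both WT arrays for the mitochondrial ribosome list (0.73 and 0.73 against -0.09 and 0.09) and the interferon list (0.95 and 0.88 against 0.02 and -0.02).

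Genes typical of long-term HSCs were lower in KO as a group. The median over 30 measured genes was -0.21 (camera adjusted p = 0.0033, and adjusted p = 0.31 with an estimated correlation), and 23 of the 30 had a lower mean. None passed over all genes in limma, with 9 lower and 1 higher at an unadjusted p under 0.05. Adjusted over the list alone 4 fell and 1 rose. The transcription factors Hlf, Prdm16 and Mecom, which maintain HSCs, were at -1.18 ± 0.18, -0.83 ± 0.17 and -0.87 ± 0.21 (SE), while Nupr1 was at 0.81 ± 0.17. Lymphoid priming genes had a median of -0.43 over 17 members (camera adjusted p = 1.3e-06, and adjusted p = 0.31 with an estimated correlation), 8 were lower at an unadjusted p under 0.05 and 7 fell adjusted over the list alone. The receptor gene Flt3 of multipotent progenitors was at -1.21 ± 0.27, Lax1 at -1.19 ± 0.22, Satb1 at -0.83 ± 0.17 and Mef2c at -0.62 ± 0.16 (SE). B lineage markers had a median of -0.18 over 15 members (camera adjusted p = 0.025, and adjusted p = 0.31 with an estimated correlation), with 1 lower adjusted over the list alone, Jchain at -1.72 ± 0.26 (SE). For the B lineage markers the adjusted p was 0.18 without WT replicate 2 and 0.088 without KO replicate 1, and the median was -0.33 without KO replicate 2. After quantile normalization it was -0.11 with an adjusted p of 0.060.

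Myeloid priming genes were higher in KO, with a median of 0.43 over 22 members (camera adjusted p = 1.3e-06, and adjusted p = 0.22 with an estimated correlation). None passed over all genes in limma, with 10 higher at an unadjusted p under 0.05, and 8 rose adjusted over the list alone. Ms4a3, a marker of granulocyte and monocyte progenitors, was at 1.13 ± 0.18, the Fc receptor gene Fcgr3 at 1.10 ± 0.17, Ly86 at 1.07 ± 0.18 and Anxa3 at 0.96 ± 0.16 (SE). Neutrophil markers, which a sort of lineage-negative cells should exclude, moved with them by a median of 0.77 over 16 members (camera adjusted p = 1.1e-06, and adjusted p = 0.31 with an estimated correlation). Of the neutrophil markers 9 were higher at an unadjusted p under 0.05, and 8 rose adjusted over the list alone. The granule protein genes Camp and Ngp were at 1.80 ± 0.26 and 1.15 ± 0.17 (SE), and S100a8 had means of 5.23 ± 0.62 in WT and 6.73 ± 0.02 in KO (log2, SD, n = 2). Without WT replicate 1 the neutrophil median was 0.43. Mast cell and basophil markers had a median of 0.27 over 15 members (camera adjusted p = 0.014, and adjusted p = 0.31 with an estimated correlation), and Gzmb, a granzyme gene, rose 3.92-fold. Adjusted over the list alone 3 of these markers rose. Without WT replicate 1 that list had an adjusted p of 0.16, among genes at or above the median level 0.13, and without KO replicate 2 its median was 0.42. Markers of T and NK cells (median -0.03) and of stroma and endothelium (median 0.03, mean -0.01) did not pass the test, with camera adjusted p-values of 0.63 and 0.90 over 15 and 18 members. With each array left out in turn their medians ran from -0.14 to 0.12 and from -0.060 to 0.061.

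Genes that hold cells in quiescence or slow the cell cycle were lower in KO as a group. Their median was -0.31 over 28 members (camera adjusted p = 1.5e-05, and adjusted p = 0.31 with an estimated correlation). None passed over all genes in limma, 11 were lower at an unadjusted p under 0.05, and 4 fell adjusted over the list alone. Cdkn1a, a cyclin-dependent kinase inhibitor, was at -0.86 ± 0.13, Nr4a2 at -1.34 ± 0.21, Egr1 at -1.11 ± 0.23 and Foxo1 at -0.78 ± 0.18 (SE). Immediate early and dissociation stress genes, which handling of cells can induce, moved with them by a median of -0.33 over 26 members (camera adjusted p = 2.6e-05, and adjusted p = 0.31 with an estimated correlation). Of them 13 were lower at an unadjusted p under 0.05, and 9 fell adjusted over the list alone. Fosb was at -0.97 ± 0.25, Fosl2 at -1.05 ± 0.28 and Egr2 at -0.82 ± 0.19 (SE). Without WT replicate 1 that list's adjusted p was 0.051, and without WT replicate 2 its median was -0.54. The lists share 4 members, Btg2, Egr1, Klf2 and Nr4a1. Without them the quiescence list had a median of -0.25 over 24 members (camera adjusted p = 0.00072, and adjusted p = 0.31 with an estimated correlation). It still held Nr4a2, Klf4 and Klf6, relatives of shared members, so it does not fully separate quiescence from the response to handling. The cell cycle brake genes Cdkn1b, Cdkn1c and Rb1 had differences smaller than their errors, at -0.12 ± 0.20, -0.0024 ± 0.23 and -0.10 ± 0.25 (SE).

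DNA replication genes were higher in KO by a median of 0.34 over 29 members (camera adjusted p = 2.6e-05, and adjusted p = 0.31 with an estimated correlation), with 9 higher at an unadjusted p under 0.05, and 3 rose adjusted over the list alone. The helicase subunit genes Gins2 and Gins1 were at 0.81 ± 0.16 and 0.87 ± 0.21, Ccne1, for cyclin E1, at 0.77 ± 0.18 and Rfc3 at 0.65 ± 0.17 (SE). The helicase genes Mcm2 to Mcm7 changed less, from -0.00057 ± 0.32 for Mcm3 to 0.33 ± 0.35 for Mcm2 (SE). Without WT replicate 2 the replication list's median was 0.076 and its adjusted p 0.17, and without WT replicate 1 its median was 0.54. Mitosis genes had a median of 0.18 over 31 members (camera adjusted p = 0.0035, and adjusted p = 0.47 with an estimated correlation), with 7 higher and 1 lower at an unadjusted p under 0.05 and 0 in limma adjusted over the list alone. Ndc80 was at 0.70 ± 0.17, Aurka at 0.63 ± 0.17, Cdk1 at 0.52 ± 0.16 and Cenpa at 0.52 ± 0.17 (SE). The 1 member lower at an unadjusted p under 0.05 was Mki67, at -0.36 ± 0.14 (SE). For the mitosis list the adjusted p was 0.11 without WT replicate 2, with a median of 0.10, and 0.088 without KO replicate 1, and the median was 0.40 without WT replicate 1. The adjusted p was 0.0502 among genes at or above the median level and 0.072 after quantile normalization, with a median of 0.087. Genes of MYC and ribosome biogenesis had a median of 0.35 over 32 members (camera adjusted p = 6.5e-06, and adjusted p = 0.31 with an estimated correlation), with 11 higher at an unadjusted p under 0.05, and 5 rose adjusted over the list alone. Nop16, Bysl, Wdr12 and Gnl3 were at 0.74 ± 0.14, 1.26 ± 0.26, 0.77 ± 0.19 and 0.66 ± 0.16 (SE). Their list median was 0.18 without WT replicate 2 and 0.53 without WT replicate 1.

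Other nuclear receptors and coregulators had a median of -0.25 over 31 members (camera adjusted p = 0.0012, and adjusted p = 0.31 with an estimated correlation), with 7 lower and 1 higher at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. The histone acetyltransferase genes Crebbp and Ep300, whose products bind SRC coactivators, were at -1.02 ± 0.15 and -0.88 ± 0.20 (SE). Ncoa2, a paralog of Ncoa3, was at -0.71 ± 0.21 and the methyltransferase gene Prmt1 at 0.64 ± 0.17. Niche adhesion and homing genes had a median of -0.19 over 24 members (camera adjusted p = 0.017, and adjusted p = 0.47 with an estimated correlation), with 7 lower and 1 higher at an unadjusted p under 0.05 and 0 in limma adjusted over the list alone. Cd44 was at -0.77 ± 0.19, Esam at -0.76 ± 0.24 and Cxcr4 at -0.37 ± 0.13 (SE). That list's adjusted p was 0.30 without WT replicate 1, 0.067 without KO replicate 1 and 0.078 without KO replicate 2, and its median was -0.38 without WT replicate 2. Genes of p53 and apoptosis had a median of -0.19 over 23 members (camera adjusted p = 0.042, and adjusted p = 0.47 with an estimated correlation), with 3 lower and 1 higher adjusted over the list alone. Bcl2l11 was at -1.01 ± 0.25, Bcl2 at -0.54 ± 0.13 and Fas at 0.67 ± 0.16 (SE). Their list's adjusted p was 0.18 without WT replicate 1, 0.096 without KO replicate 1 and 0.27 without KO replicate 2, with medians of -0.039, -0.11 and -0.19, and its median was -0.30 without WT replicate 2. The adjusted p was 0.073 with the replicate block, 0.068 with the mean of each gene's probe sets and 0.064 with camera on ranks. Genes of IGF, PI3K and mTOR signalling (median -0.19, adjusted p = 0.20) and of autophagy (median 0.07, mean -0.01, adjusted p = 0.91) did not pass the camera test. In the first of these lists Eif4ebp1 had means of 7.19 ± 0.15 in WT and 8.20 ± 0.02 in KO (log2, SD, n = 2), and Irs2 was at -1.19 ± 0.26 (SE). Without WT replicate 2 that list's adjusted p was 0.0051 with a median of -0.36, and without WT replicate 1 the median was 0.093. The autophagy median was -0.013 after quantile normalization, and -0.039 to 0.14 with each array left out in turn.

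The named genes that fell most were immunoglobulin V segments, which encode the variable parts of antibody chains. Igkv15-103 fell 42.8-fold, from 8.96 ± 0.11 to 3.54 ± 0.02 (log2, SD, n = 2, limma adjusted p = 0.00060). Igh-VS107 fell 9.58-fold and Igkv4-91 7.97-fold. Another kappa V segment fell 9.43-fold, with an adjusted p of 0.054 without WT replicate 1. Many V segments have close copies within their own family, so a probe set may share signal with those copies. Emp1, for an epithelial membrane protein, fell 4.03-fold, though its mean over all probe sets differed by -1.15 with an adjusted p of 0.076. Il1r2, the decoy receptor of interleukin 1, fell 2.95-fold, and the orphan nuclear receptor gene Nr4a3 2.56-fold. The transcription factor gene Zbtb20 fell 2.83-fold. The non-coding RNA genes Lncpint, Mir1931 and Mir26a-1 fell 4.05-fold, 3.61-fold and 2.90-fold. Ifna4, Fam209 and Samd11 fell 3.12-fold, 3.84-fold and 2.90-fold. Among the remaining increases, Ces2g, a carboxylesterase gene, rose 11.5-fold and Nxpe2 7.31-fold. The metallothionein gene Mt2 rose 6.46-fold, Atp1b2, a sodium pump subunit gene, 6.23-fold and the mitochondrial carrier gene Slc25a21 5.41-fold. Ces2g, Mt2 and Ifna4 also belong to families of close copies.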

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

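The test in this part was run on data that the comparisons above do not use, and it was chosen after the file had been seen. Among the 17824 probe sets that the annotation gives several genes or does not list, 5 differed between KO and WT past the limma threshold, 1 higher and 4 lower. At an unadjusted p under 0.05 there were 2953 such probe sets, and 989 changed at least 1.5-fold at an unadjusted p under 0.01. Probe set 17459338 was at 10.5 in WT and 2.04 in KO, a difference of -8.44 ± 0.25 (log2, SE, limma adjusted p = 0.013). Probe set 17467384 differed by -8.32 ± 0.30, with means of 9.84 and 1.52. Probe set 17549906 was higher in KO by 5.11 ± 0.26, at 8.59 against 3.48. No gene is named for them here.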

How the results depend on the processing

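The restriction to protein-coding genes and the removal of the span trend were chosen after the data were seen. Among the lists and the genes that the naming rule took, none that was called changed direction under any alternative. The 88 higher and 25 lower genes became 208 and 81 among genes at or above the median level, where fewer genes were tested, 196 and 51 after median centring, 165 and 50 with array weights, and 138 and 62 with the span trend removed. Lower genes numbered 61 after quantile normalization and 14 among protein-coding genes, where non-coding genes and V segments were left out. With the replicate block the counts were 83 and 28, of which 89 genes were shared with the main 113, and it ended the calls of Nr4a3, Mrpl17, Bst2 and Tspan33 and of the p53 list, whose adjusted p was 0.073. The correlation of same-numbered arrays was 0.11 and 2 pairs cannot show pairing. Leaving out single arrays gave 0 to 1730 higher and 0 to 1272 lower genes, 173 to 1417 and 103 to 1098 genes in the looser count, and an Ncoa3 difference of -2.54 to -1.83. When an array is left out, the lone array of its genotype is assumed to vary like the remaining pair, and the KO pair differed less than the WT pair. Of 25 lists past camera, 0 passed with the estimated correlation. There the smallest adjusted p was 0.22 and 5 lists had an unadjusted p under 0.05. That setting tests each list on the few residual degrees of freedom that 4 arrays leave, so its losses do not measure correlation alone. The interferon list had an estimated correlation of -0.019, below the preset 0.01, yet its camera p went from 8.3e-15 to 0.013 before adjustment. Of the 25 lists 5 passed fry, which does not compare a list with other genes. In the other alternatives 14 of the 25 lists passed each time and 31 list calls were lost. Among them the filter at the median level ended the calls of mitosis, mitochondrial biogenesis, fatty acid oxidation, macrophage and mast cell lists, and quantile normalization those of mitosis, mitochondrial biogenesis and B lineage lists. The mean of a gene's probe sets ended the call of the p53 list, and camera with ranks those of the p53 and macrophage lists. Over the named genes other than Ncoa3, 105 calls were lost and 201 gained, mostly when an array was left out. A sign changed without a call in 6 gene and 18 list cases. Leaving out probe sets by name suffix was not run, and lists were not tested on single probe sets. With 2 arrays per group, a gene changed by 1 on the log2 scale was recovered in 14.0% of simulated cases.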

Other observations

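The gene sets of the first paragraph, the tests of the span trend and of the spread between arrays on oxidative phosphorylation, of a lower share of sorted cells, of B lineage cells, of V segment sequence and of the array splits, and the rule that Slc4a1 must lie at or above the median gene to decide, were chosen after the results they measure had been seen. None of the gene sets was tested for enrichment. Of 81 small nucleolar RNA genes, 19 were higher and 7 lower by at least 1.5-fold at an unadjusted p under 0.01, or 32.1% against 6.31% of all genes. Snord52 rose 3.92-fold, Snord43 3.96-fold and Snord99 2.56-fold (limma adjusted p = 0.015, 0.018 and 0.041), while Snora23 was at -0.88 ± 0.13 and Snord71 at -1.07 ± 0.19 (SE). Of 478 microRNA genes, 5 were higher and 26 lower by that count, or 6.49%. Of 38 proteasome subunit genes, 7 were higher and 0 lower by it, or 18.4%. At an unadjusted p under 0.05 in limma 28 of the 38 were higher and 0 lower, with a median of 0.48 on the log2 scale, and 0.36 after quantile normalization. Among 18 immunoglobulin V segments, 9 were lower and 1 higher in the looser count, and the one higher was Iglv1 at 1.03 ± 0.21 (SE). Among the 25 genes on each side of Ncoa3 on its chromosome, 2 were lower and 0 higher in the looser count, Eya2 at -1.23 ± 0.21 and Adnp at -0.77 ± 0.18, and at an unadjusted p under 0.05 limma had 5 lower and 1 higher.

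Of the 3 splits of the 4 arrays into pairs, 1, the real one, gave as many as 1400 genes in the looser count, and the highest of the others gave 63. Each other split puts 1 WT and 1 KO array in both groups, so a genotype difference adds to the spread within groups and lowers the count. With 3 splits the share cannot fall under 0.05.

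Lists of mitochondrial ribosome and oxidative phosphorylation genes were higher in KO by camera at the preset correlation (adjusted p = 0.31 for both with an estimated correlation). Among genes at or above the median level the shortest genes by genomic span differed by a median of 0.16 and the longest by -0.18, while the WT arrays differed from each other along the same trend, by -0.14 and 0.17 (WT 1 minus WT 2). After a trend with span was removed from each array, the mitochondrial ribosome median was still 0.64. That decides little, because the trend was fitted over all genes, where the shortest and longest differed by only 0.03 and -0.10. Random lists matched on expression and span had a median of 0.24 and reached at most 0.50, against the observed 0.72. This argues against a trend with gene span as the whole cause for the mitochondrial ribosome list. However, genes drawn at random need not share the list's estimated correlation of 0.19. For oxidative phosphorylation the span trend stays open. The median was 0.39 after the same removal, and the observed 0.45 lay at percentile 99.96 of 10000 matched random lists. Their median was 0.26 and their highest 0.48, and such lists need not share the estimated correlation of 0.35 among these genes. A general gain of compact abundant transcripts may account for part of both, since cytosolic ribosomal protein genes had a median of 0.20, less than the mitochondrial value but not near 0. Differences between single samples stay open too. The WT arrays differed in the mitochondrial ribosome list by 0.26 of the KO minus WT difference. In the oxidative phosphorylation list they differed by 0.48 of it. A change in the knockout cells themselves also stays open. Matched random lists were drawn for these 2 lists only. The medians of other lists, such as -0.21 for long-term HSC genes and 0.17 for fatty acid oxidation genes, were not set against such lists. The medians of fatty acid oxidation, mitosis (0.18) and mitochondrial biogenesis genes (0.25) did not exceed 0.26, the median of random lists matched to oxidative phosphorylation. A rise beyond that of other expressed genes was thus not shown for these lists. Proteasome genes, at 0.48, differed by as much as tricarboxylic acid cycle genes, at 0.43.

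Lists of erythroid, myeloid and interferon genes were higher in KO by camera at the preset correlation and the stem cell list lower, with adjusted p = 0.22 for the first 3 and 0.31 for the last with an estimated correlation. An entry of all other cell types alike would raise the markers of each. Over the members at or above the median gene, however, 3 of the 8 lists of other cells had a median under 0.1, with B lineage markers at -0.36. Those 3 lists rest on 5 to 7 such members each. Markers of neutrophils and erythroblasts were at 1.02 and 0.86. Members were kept by the mean of their higher group, so some passed only through their level in KO. Over all measured members these 2 medians were 0.77 and 0.74. These values do not speak against an entry of particular cells, and neutrophils in the KO sort stay open. Mature erythroblasts in the KO sort may have contributed and stay open: the 8 erythroblast markers outside the priming list had a median of 0.73, while Slc4a1, an abundant gene of such cells, differed by -0.96 ± 0.24 (SE) but decides little, because at 4.27 in WT and 3.30 in KO it lay below the median gene in both groups. It also remains open whether early erythroid and myeloid progenitors made up more of the KO cells or whether the same cells had more of these transcripts. The level of Sca-1, which the sort used and which interferon can induce, was not analysed here. Kit, the gene of the sort marker c-Kit, was at -0.60 ± 0.23 (SE, limma adjusted p = 0.25).

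Of the 18 immunoglobulin V segments 5 fell past the threshold, with Igkv15-103 at -5.42 on the log2 scale, and 12 had a lower and 6 a higher mean in KO. A sort of lineage-negative cells should exclude B lineage cells. Fewer B lineage cells in the KO sort stay open. Of the 15 B lineage markers 7 lay at or above the median gene, with a median of -0.36. The others were too dim to decide. The V segments moved unevenly, however, with Igkv5-43 at -1.28 ± 0.12 and Iglv1 at 1.03 ± 0.21 (SE) beside Igkv15-103. An even loss of B lineage cells alone does not account for that spread. Jchain, which antibody-secreting cells express, was at -1.72 ± 0.26 (SE), and a few such cells in the WT sort were not tested. Sequence differences between the mice at these loci, which could change probe binding, cannot be told apart from a change in transcription, as 1 V segment was higher and 9 were lower.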
